A study of Mus musculus with 9 samples.

How the data were processed

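Poly(A)-enriched liver RNA from C57BL/6 mice was made into barcoded libraries with an Ion Torrent total RNA kit, amplified and sequenced on an Ion Torrent Proton instrument, per the labels' protocols. The labels give 3 mice per group, treated for 9 weeks, in 3 groups: normal diet with vehicle, high fat diet with vehicle, and high fat diet with B-LGND2. Doses, the composition of the diets, sex and the hour of collection are not given in the sources used here. The counts point to male mice: per library, the Y-linked Ddx3y had 120 to 337 counts and the female-specific Xist 0 to 2. Per the submitters' processing notes, the tools were TopHat2 2.0.13, Bowtie2 2.2.4, SAMtools 0.1.19, HTSeq 0.6.1p1 and DESeq2 1.6.3, with the mouse build GRCm38.p3. The annotation release, the strand setting and the mode of read assignment are not given in the sources used here.

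The authors deposited a single table of raw read counts per gene, whole numbers without normalization, with 45513 Ensembl gene IDs and 1 column for each of the 9 libraries. Each column was matched to its library by name. Symbols, biotypes, coordinates, transcript lengths and GC content were taken from GENCODE release M21 on GRCm38, matched by gene ID: 44585 IDs had a symbol and 928 had none, which stayed in the tests under their ID. Coordinates are 1-based gene spans. The table held no lines for unassigned or ambiguous reads, so the share of reads outside genes is unknown. Library totals ran from 5778978 to 10322972 counts. Counts are not molecules, since the libraries were amplified and carry no molecular identifiers. Intervals and floors of read counts cover counting error only.

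Counts were analysed in R 4.3.3. Low-count genes were removed with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 12102 genes and at least 99.7% of the counts of each library. Library sizes were scaled with the trimmed mean of M-values (TMM). One quasi-likelihood model with robust dispersions and a term for group was fitted to all 9 libraries, which share one estimate of the spread (6 residual degrees of freedom), and 3 two-sided contrasts were tested: high fat against normal diet under vehicle, B-LGND2 against vehicle on the high fat diet, and B-LGND2 on the high fat diet against vehicle on normal diet. Benjamini-Hochberg adjustment ran over all genes tested in a contrast, with a threshold of 0.05, and SEs were derived from the fold change and its F statistic. Levels are counts per 1e6 counts (CPM) on TMM-scaled library sizes, as mean ± SD of 3 libraries. An exact permutation test of a single value between groups of 3 cannot give a p below 0.1, so none was run on single genes.

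Gene lists for pathways, cell types and sample quality were fixed before the data were examined, as were the groups, tests, alternatives and rule for named genes. Of 40 lists, the 35 with at least 3 members tested were compared with the other genes by camera of limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast. No list kept its call with an estimated correlation. The directional rotation test fry, which asks whether a list's genes move on balance one way and makes no comparison with other genes, called 0, 7 and 7 lists in the 3 contrasts, of which 0, 5 and 5 were also called by camera. Counts of list members are given over all genes tested and adjusted over the list alone.

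Genes were named by rule: per contrast, among called genes with an average log2 CPM of at least 1 and no overlap between the libraries of both groups, the 10 largest rises and 10 largest falls (5 and 5 in the third contrast), leaving out predicted genes, pseudogenes and clone names; for each called list and for 7 lists of lipid metabolism, inflammation, matrix and respiration, up to 4 members with the smallest p; the estrogen receptor genes; and the 10 genes called for diet and B-LGND2 in opposite directions with the smallest p. Other list members and counterparts named beside them were chosen after their values were seen.

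For the opposite directions of diet and ligand effects, 50 data sets were simulated in which called genes carried their diet effect and no gene a ligand effect. The test was checked on simulated counts with the means, dispersions and library sizes of the real data: for the diet contrast it recovered 19.2% of genes changed by 1 on the log2 scale and 89.0% of those changed by 2, with 4 false calls among 11901 genes, and for the ligand contrast 30.6% and 90.0%, with 5 false calls among 11885 genes. This check was run with 2 random seeds and the values are those of the last run. Alternatives were DESeq2 size factors, no scaling, no filter, a filter of 50 counts in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, dispersions without the robust option, only the 2 groups compared, the replicate number as a block, an estimated correlation for lists, and each library left out in turn. After the data were seen, 3 more were added: offsets that remove each library's trend on transcript length and GC content, protein-coding genes only, and the log2 rRNA share as a covariate. No library was left out of the results, and 0 columns lacked a sample.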

Results

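Liver RNA of C57BL/6 mice was sequenced after 9 weeks of diet and treatment. The 9 libraries formed 3 groups of 3: normal diet with vehicle, high fat diet with vehicle, and high fat diet with B-LGND2, a compound known here only by its code name that the series title presents as a ligand of estrogen receptor beta. Total counts per library ran from 5778978 to 10322972, with both ends in the B-LGND2 group. No 2 libraries were alike within sampling noise: the smallest chi-square per degree of freedom between any pair was 13.02. The labels give 3 mice per group and name no batch, and p-values measure the spread between these samples. Of 45513 annotated genes, 23996 had no count in any library and 12102 were tested.

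The groups differed in library composition, beside which every gene group described here has to be read. Gene models annotated as ribosomal RNA (rRNA) took 3.42% ± 0.299 of counts on normal diet, 1.20% ± 0.275 on high fat diet with vehicle and 5.52% ± 1.04 with B-LGND2 (mean ± SD, n = 3 each), and no library of one group overlapped another group. Nearly all of these counts lay in one model, CT010467.1 (chr17:39846353-39848827, GRCm38). The Spearman correlation across genes between a library's deviation from the mean log expression and transcript length was 0.337 ± 0.0195 on high fat diet with vehicle, -0.163 ± 0.351 on normal diet and -0.0219 ± 0.193 with B-LGND2. Genes are not independent replicates, so these correlations describe the libraries. Replicate 1 of the normal diet group stood apart in mitochondrially encoded transcripts, with 12.7% of counts against 3.69% to 6.12% in the other libraries, and replicate 3 of that group had the lowest length correlation, -0.516. The same correlation with GC content was 0.521 in B-LGND2 replicate 1 and at most 0.0825 in the other libraries. Across protein-coding genes, the log2 fold change correlated with GC content at 0.133 for diet, 0.263 for B-LGND2 against vehicle and 0.411 for treated livers against normal diet. In the same order, its correlation with transcript length was 0.441, -0.280 and 0.150.

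**Figure D1:**
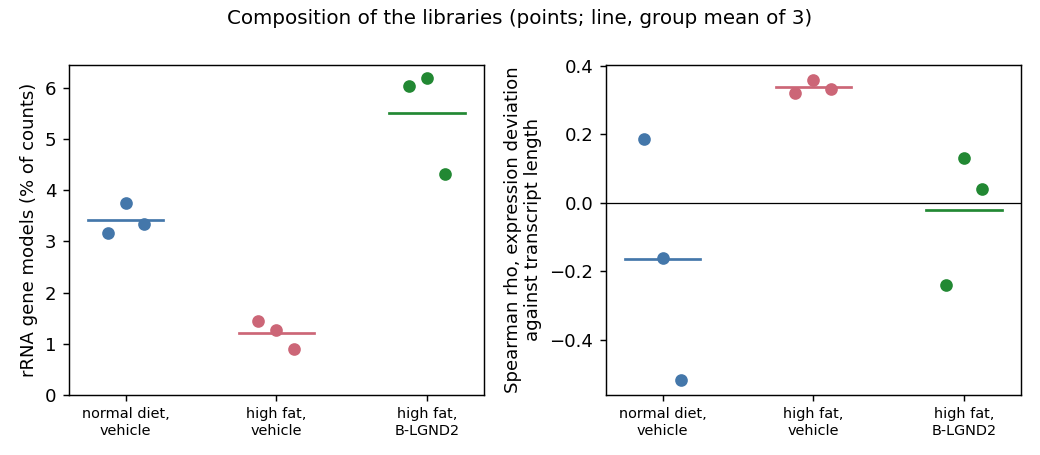
Percent of counts in rRNA gene models (left) and Spearman correlation of expression deviation with transcript length (right) in each library of the 3 groups; points are libraries and lines are group means of 3. The rRNA share of the high fat vehicle libraries lay between 0.901% and 1.44%, below every library of the other groups, and their length correlations lay above all others.

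Among the receptors through which an estrogenic ligand could act, only Esr1, encoding estrogen receptor alpha, was detected at depth. Esr2, encoding estrogen receptor beta (chr12:76120419-76177259), had 0 counts in each of the 9 libraries, which allows up to 3 counts per library, and Gper1, encoding a membrane estrogen receptor, had 3 counts over all libraries. Esr1 (chr10:4611593-5005614) had 151, 156 and 209 counts on normal diet, 139, 107 and 82 on high fat diet with vehicle, and 238, 253 and 267 with B-LGND2. It stood at 36.4 ± 8.47 counts per 1e6 (CPM) with B-LGND2 against 16.8 ± 5.78 in high fat vehicle livers (log2 fold change 1.12, SE 0.27, adjusted p = 0.0287 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in 3 of 3 libraries). That call was lost without scaling beyond library size, and in 3 of the 9 fits that left out a library, with an adjusted p of up to 0.135. On high fat against normal diet under vehicle the log2 fold change of Esr1 was -0.64 (adjusted p = 0.183).

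The comparison of the vehicle groups asks what the high fat diet did to liver expression. Cyp3a11, a major hepatic cytochrome P450 of drug metabolism (chr5:145854426-145879964), fell on the high fat diet from 2426 ± 584 to 134 ± 39.2 CPM, an 18.1-fold change (n = 3 per group), and Gstm3, a glutathione transferase, from 97.4 ± 6.49 to 21.5 ± 1.97 CPM. Cyp51, the lanosterol demethylase of sterol synthesis, fell to 50.6 ± 28.3 from 190 ± 36.6 CPM. Among single genes, Zbtb16, a zinc finger transcription factor (chr9:48654297-48836222), rose 5.28-fold, from 14.9 ± 5.58 to 78.5 ± 7.98 CPM, Per1, a core clock repressor, rose from 28.5 ± 3.60 to 72.3 ± 8.14 CPM, and Lpin1, a phosphatidate phosphatase and transcriptional coactivator, rose from 296 ± 112 to 1004 ± 159 CPM. Lpl, encoding lipoprotein lipase, fell from 15.1 ± 3.95 to 2.88 ± 0.792 CPM.

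In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 362 of 12102 genes passed an adjusted p of 0.05, 182 higher and 180 lower on the high fat diet. Of these, 168 and 124 were protein coding, and 9 and 46 were pseudogenes. The libraries of both groups did not overlap in 360 of the 362, and in 30.1% of all genes tested, where chance gives 10%. The largest rises were in Cyp2b9 (log2 fold change 3.41, SE 0.82), Mdm1 (3.17, SE 0.74), Gna14 (2.93, SE 0.41), the glucose transporter gene Slc2a4 (2.81, SE 0.69), Lrfn4, Plppr3, Inhbb and the mitochondrial tRNA gene mt-Tq, followed by Zbtb16 (2.40, SE 0.27) and Rgs16 (2.26, SE 0.34). Adjusted p ranged from 2.29e-04 for Zbtb16 to 0.0455 for Cyp2b9. Cyp2b9 had 1, 1 and 28 counts on normal diet and 138, 126 and 42 on high fat diet with vehicle. The size of its rise therefore depends on single libraries. Cyp3a11 had the largest fall (-4.18, SE 0.29, adjusted p = 9.70e-07), followed by Snord118 (-3.50, SE 0.87), Lars2 (-3.08, SE 0.31), Pdzk1ip1, Cyp2c55 (-2.74, SE 0.43), Cyp4a12a (-2.53, SE 0.31), Rpph1, Clec2h, Lpl (-2.39, SE 0.32) and Cyp3a59 (-2.32, SE 0.39). Lars2, a mitochondrial leucyl-tRNA synthetase gene (chr9:123366927-123462666), was lower in the high fat vehicle libraries than in every library of the other groups, as was the rRNA share. Members of the Cyp2b, Cyp3a, Cyp4a and Gstm families are near-identical to neighbours, so the split of reads between them is uncertain. The models of Plppr3 and Prtn3 share the stretch chr10:79874476-79874634, and no strand setting is given in the sources used here.

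Of the 35 gene lists tested, 6 passed camera (limma) in this comparison. Sterol synthesis and uptake genes were lower as a group: 3 of 24 fell (Cyp51 -1.91, SE 0.31; Mvd -1.70, SE 0.42; Msmo1 -1.07, SE 0.28) and none rose, 13 were lower when adjusted over the list alone, and the median log2 fold change was -0.79 (camera adjusted p = 2.25e-07). Dhcr7 stood at -0.94 and did not pass (edgeR adjusted p = 0.0531). In the xenobiotic list, 6 of 20 fell and none rose, among them Cyp3a11, Gstm3 (-2.18, SE 0.24) and the carboxylesterase Ces2a (-1.16, SE 0.24). Adjusted over the list alone, 10 were lower and 3 higher, with a median of -0.38 (camera adjusted p = 7.22e-05). With a correction for transcript length and GC content the median of the xenobiotic list shrank to -0.09, though its camera call was kept. Of 14 male-biased liver genes, Cyp4a12a and Cyp4a12b fell (-2.53 and -1.54), 4 were lower adjusted over the list alone, and the median was -0.29 (camera adjusted p = 0.0102). That last call was lost with a correction for transcript length and GC content (adjusted p = 0.459), without normal diet replicate 1 (0.181) and without high fat vehicle replicate 2 (0.0634). With an estimated correlation the adjusted p of these 3 lists was 0.604, 0.548 and 0.812.

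Clock, immediate early and gluconeogenic genes were higher as groups. Per1 (log2 fold change 1.35, SE 0.22), Per2 (1.36, SE 0.28) and Nfil3 (1.43, SE 0.32) rose among 16 clock genes, 6 were higher adjusted over the list alone, and the median was 0.54 (camera adjusted p = 5.36e-05). Cry2 stood at 0.79 and did not pass (edgeR adjusted p = 0.0677). Among 15 immediate early and heat shock genes, which also respond to handling of tissue, Junb (1.52, SE 0.30), Jun (1.62, SE 0.33) and Btg2 (1.22, SE 0.27) rose and 6 were higher adjusted over the list alone, with a median of 0.71 (camera adjusted p = 6.17e-04). Among 16 genes of gluconeogenesis and the insulin response, Tat, a tyrosine aminotransferase (1.44, SE 0.26), Pck1, the cytosolic phosphoenolpyruvate carboxykinase (4950 ± 483 against 2216 ± 762 CPM; 1.16, SE 0.26), and Foxo1 (0.86, SE 0.21) rose. Adjusted over the list alone, 5 were higher and 1 lower, with a median of 0.62 (camera adjusted p = 6.17e-04). With an estimated correlation the adjusted p of these 3 lists was 0.548, 0.548 and 0.565.

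Lists of lipid handling did not move in one direction as groups. The mixed form of fry, which counts moves either way and makes no comparison with other genes, did pass. Its adjusted p was 1.7e-04 for lipogenesis, 6.9e-05 for fatty acid oxidation and 7.5e-05 for lipid droplets and uptake. Among 19 lipogenic genes Lpin1 rose (1.76, SE 0.28) and the malic enzyme Me1 fell (-1.87, SE 0.46), with 3 higher and 1 lower adjusted over the list alone and a median of 0.06 (camera adjusted p = 0.512). Among 23 genes of fatty acid oxidation, Ppara, the transcription factor that drives the pathway (203 ± 26.2 against 83.7 ± 31.7 CPM; 1.28, SE 0.28), and Acadvl (0.83, SE 0.22) rose while Cyp4a10 fell (-1.89, SE 0.45), with a median of 0.22 (camera adjusted p = 0.245). Plin4 rose (1.83, SE 0.40) and Lpl fell in the lipid droplet and uptake list, whose median of -0.11 turned to 0.08 without scaling (camera adjusted p = 0.791). None of 12 inflammation genes passed edgeR's test, with 1 under an unadjusted p of 0.05 and 1 called by DESeq2; Cxcl1, a neutrophil chemokine, stood at 1.85 (edgeR adjusted p = 0.0668) and the list median at 0.23 (camera adjusted p = 0.791). None of 17 matrix genes passed (3 under an unadjusted p of 0.05, 0 by DESeq2), with a median of 0.02 that turned to -0.13 with the length and GC correction (camera adjusted p = 0.923). Nuclear subunits of oxidative phosphorylation had a median of -0.27, turning to 0.05 with that correction, and none of 27 passed edgeR (7 under an unadjusted p of 0.05, 2 by DESeq2; camera adjusted p = 0.113). Macrophage markers had a median of -0.15, which turned to 0.03 without scaling, and none of 14 passed (2 under an unadjusted p of 0.05, 0 by DESeq2; camera adjusted p = 0.791).

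The number of genes called for diet depended on single libraries. It was 35, 66 and 39 without high fat vehicle replicate 1, 2 or 3, and 1860, 89 and 79 without normal diet replicate 1, 2 or 3. Of 54 named calls, 15 were kept with any 1 of the 9 libraries left out, among them Cyp3a11, Zbtb16, Gna14, Rgs16, Gstm3, Per1, Lpin1, Lpl, Cyp2c55 and Cyp4a12a, while for the others the adjusted p reached up to 0.278 (Me1). With the rRNA share of each library as a covariate edgeR called 0 genes, with 486 under an unadjusted p of 0.05. Transcript length moved with the calls: the median length of protein-coding genes that rose was 4562.5 bases and of those that fell 1997.5, against 3426 over all protein-coding genes tested. Without scaling beyond library size the median log2 fold change of all genes was 0.17 and the calls split into 260 higher and 98 lower, 72.6% higher against 50.3% with scaling.

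**Figure D2:**
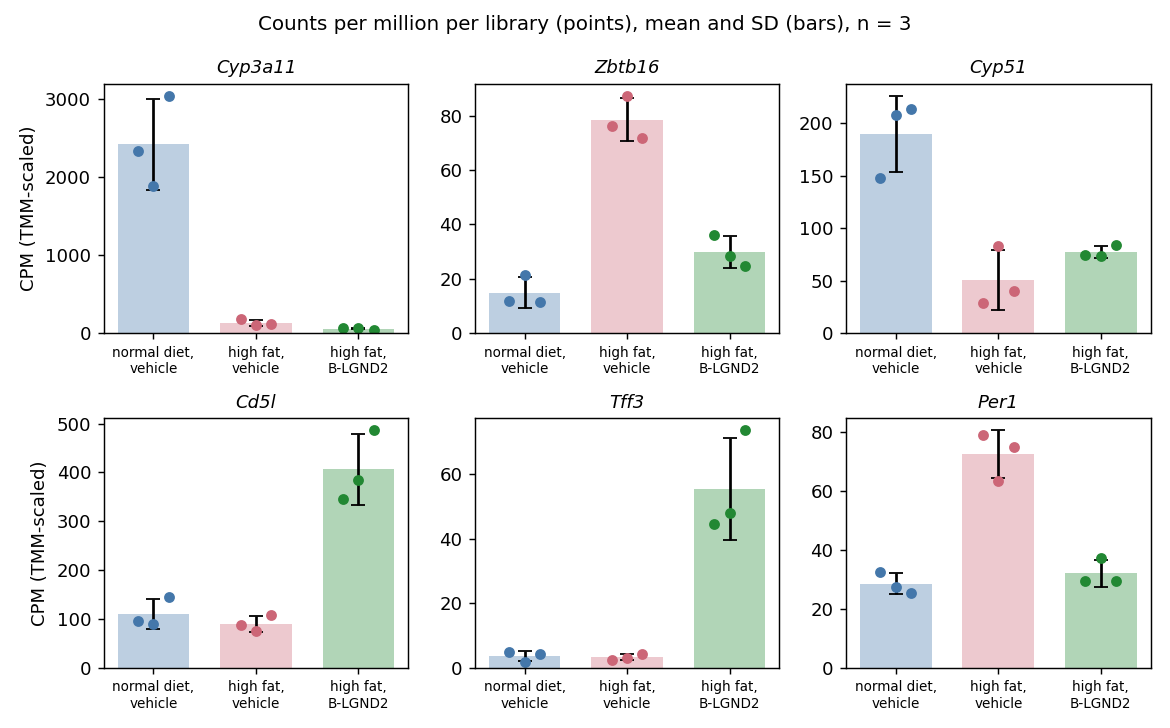
Expression of Cyp3a11, Zbtb16, Cyp51, Cd5l, Tff3 and Per1 in CPM on library sizes scaled by the trimmed mean of M-values, per group; points are libraries, bars the means of 3 and error bars the SD. Cyp3a11 stood at 2426 CPM on normal diet, 134 on high fat diet with vehicle and 56.3 with B-LGND2, and Cd5l at 110, 90.1 and 406 CPM.

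B-LGND2 was compared with vehicle among mice on the high fat diet, to find what the ligand changed. Genes of resident liver macrophages were higher with B-LGND2: Cd5l, a secreted macrophage protein, stood at 406 ± 72.2 against 90.1 ± 16.8 CPM, a 4.51-fold rise (n = 3 per group), and C1qa, C1qb and C1qc, the chains of complement component C1q, rose 4.55-, 3.70- and 3.29-fold. Marco, a macrophage scavenger receptor (chr1:120474538-120505024), rose from 27 counts in 3 libraries to 56, 228 and 54 counts. Tff3, a secreted trefoil peptide (chr17:31125306-31129646), rose 16.5-fold to 55.3 ± 15.9 CPM, and Prtn3, the myeloid serine protease proteinase 3 (chr10:79874476-79883174), 41.3-fold to 34.1 ± 11.9 CPM. Cyp3a11 fell to 56.3 ± 10.2 from 134 ± 39.2 CPM and Acadvl, the very long chain acyl-CoA dehydrogenase of fat oxidation, to 33.7 ± 4.18 from 86.3 ± 8.16 CPM. Per1 fell to 32.0 ± 4.57 from 72.3 ± 8.14 CPM.

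By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 681 genes passed, 371 higher and 310 lower with B-LGND2. Of these, 306 and 284 were protein coding, and 53 and 9 were pseudogenes. The groups did not overlap in 674 of the 681, and in 33.6% of all genes tested, where chance gives 10%. The largest rises were in Slc34a2, a phosphate transporter gene (log2 fold change 5.62, SE 1.13, adjusted p = 0.0189, with 34.0 CPM in replicate 2 and 3.01 and 3.00 CPM in the other libraries), Prtn3 (5.37, SE 0.56, 1.02e-04), Tff3 (4.04, SE 0.35, 1.84e-05), Myo15b (3.96, SE 0.68), Mmd2 (3.79, SE 0.34), Marco (3.57, SE 0.59), Lars2 (3.22, SE 0.31), Dntt, Ptgds and Isyna1, an inositol phosphate synthase gene (2.80, SE 0.35). The largest falls were in Cyp2b9 (-5.34, SE 0.99, adjusted p = 0.0133, chr7:26173411-26210661), the mitochondrial tRNA genes mt-Tq and mt-Tp, Mdm1 (-3.12, SE 0.73), Tgfbr3l, Trp53inp1 (-2.82, SE 0.39), Erbb4, Clic5, the orphan nuclear receptor gene Esrrg (-2.57, SE 0.44) and the immediate early gene Egr1 (-2.49, SE 0.59). Of 2 other neutrophil granule genes, looked at after the values of Prtn3 were seen, Mpo had 0 counts in all libraries and Elane 1, 1 and 7 counts over the normal diet, high fat vehicle and B-LGND2 libraries, too few to compare, where Prtn3 had 42, 16 and 740.

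Macrophage markers formed the list with the smallest p. All 14 tested members, of 17 listed, were higher with B-LGND2, 10 rose in edgeR's test, 13 were higher adjusted over the list alone, and the median log2 fold change was 1.504 (camera adjusted p = 2.05e-19; adjusted p = 0.0723 with an estimated correlation). Beside Cd5l (2.17, SE 0.25) and C1qa (2.19, SE 0.27), Lyz2 (2.03), Adgre1, encoding F4/80 (1.59), Csf1r, the receptor of macrophage colony-stimulating factor (1.42), Vsig4 (1.35) and Clec4f (1.24) rose, with edgeR adjusted p from 1.89e-04 for Cd5l to 0.0220 for Adgre1. Timd4 (1.22), Cd68 (1.10), Ctss (0.75) and Mpeg1 (0.29) were higher without passing. Antigen presentation genes were higher as a group, with H2-Eb1 (1.31, SE 0.37) and H2-DMb1 (2.03, SE 0.58) rising among 12, 7 higher adjusted over the list alone and a median of 0.78 (camera adjusted p = 0.00333; adjusted p = 0.607 with an estimated correlation). Among 20 interferon response genes Bst2 rose (1.08, SE 0.28), 5 were higher adjusted over the list alone and the median was 0.29 (camera adjusted p = 0.0437; adjusted p = 0.607 with an estimated correlation). The antigen presentation call was lost without B-LGND2 replicate 3 (adjusted p = 0.0797), and the interferon call without any normal diet library (0.0564, 0.0734 and 0.0826 in turn), high fat vehicle replicate 1 (0.0871) or 2 (0.113), or B-LGND2 replicate 3, where its median was -0.00477 (0.279).

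Kdr, a receptor of endothelial growth factor, rose (0.91, SE 0.25) among 11 endothelial markers, of which 5 were higher adjusted over the list alone, with a median of 0.50 (camera adjusted p = 0.00514; adjusted p = 0.451 with an estimated correlation). Spp1, encoding osteopontin (0.95, SE 0.22), and Sparc (0.90, SE 0.25) rose among 17 matrix genes, 2 were higher adjusted over the list alone, and the median was 0.46 (camera adjusted p = 0.0118; adjusted p = 0.513 with an estimated correlation). The matrix call was lost without high fat vehicle replicate 3 (adjusted p = 0.145) or B-LGND2 replicate 1 (0.103). Col1a1, the chain of type I collagen, stood at 1.18 (edgeR adjusted p = 0.144). None of 10 stellate cell markers passed edgeR (4 under an unadjusted p of 0.05, 2 by DESeq2), with a median of 0.57 (camera adjusted p = 0.0984). Hepatocyte markers had a median of 0.04, which turned to -0.14 without scaling, and none of 12 passed (4 under an unadjusted p of 0.05, 1 by DESeq2; camera adjusted p = 0.906).

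**Figure D3:**
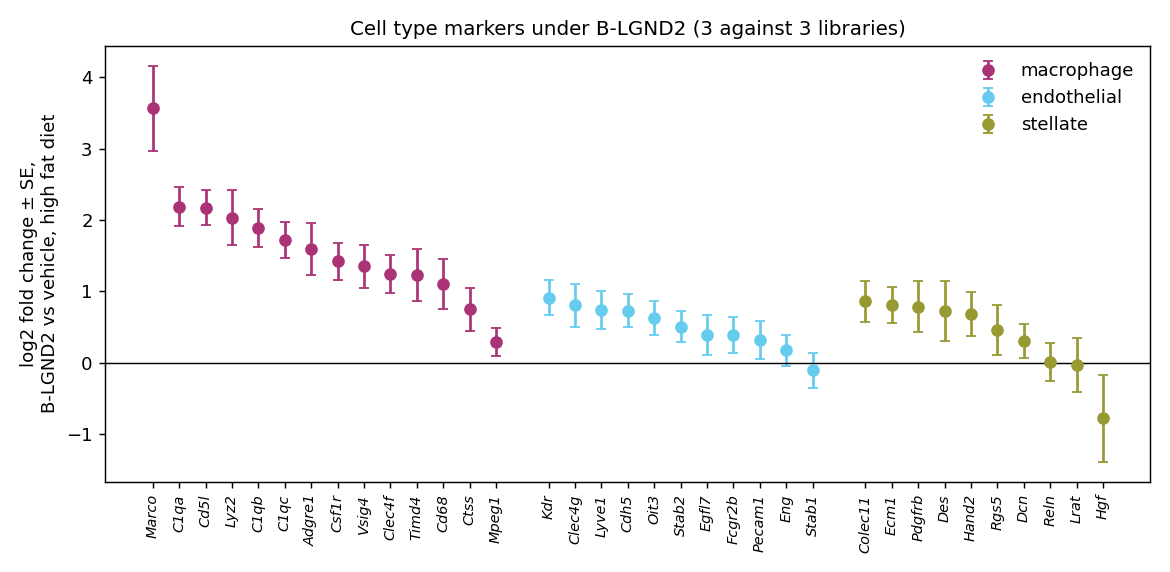
Log2 fold change of B-LGND2 against vehicle on high fat diet for 14 macrophage, 11 endothelial and 10 stellate cell markers; points are genes and bars the SE from edgeR's fit. The medians were 1.504, 0.50 and 0.57, and no macrophage marker lay below 0.29.

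Lists of oxidation, drug metabolism and the clock were lower. In the xenobiotic list Cyp3a25 (-1.57, SE 0.24), Cyp3a11 (-1.25, SE 0.26), the bilirubin glucuronosyltransferase Ugt1a1 (-0.90, SE 0.20) and Alas1 (-0.87) fell, whereas Gstm3 (1.27, SE 0.24) and Gstm1 (1.25) rose, with 13 lower and 2 higher adjusted over the list alone and a median of -0.85 over 20 genes (camera adjusted p = 1.78e-04; adjusted p = 0.367 with an estimated correlation). Among 23 genes of fatty acid oxidation, Acadvl (-1.36, SE 0.22) and Hadhb (-1.82, SE 0.42) fell, 3 were lower adjusted over the list alone and the median was -0.38 (camera adjusted p = 0.00146; adjusted p = 0.367 with an estimated correlation). Per1 (-1.18, SE 0.22) and Ciart (-1.08, SE 0.28) fell among 16 clock genes, 5 were lower adjusted over the list alone and the median was -0.49 (camera adjusted p = 0.00118; adjusted p = 0.367 with an estimated correlation). Junb (-1.95), Egr1, Btg2 (-1.04) and Zfp36 (-0.97) fell among 15 immediate early and heat shock genes, whose median was -0.35 (camera adjusted p = 0.112).

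Lipid synthesis, inflammation and respiratory chain lists did not pass camera. Lpin1 (-1.11, SE 0.27) and Mlxipl, encoding the carbohydrate response factor ChREBP (-1.34, SE 0.35), fell among 19 lipogenic genes with a median of -0.05 (camera adjusted p = 0.726). None of 24 sterol synthesis and uptake genes passed edgeR (4 under an unadjusted p of 0.05, 0 by DESeq2), with Mvd at 1.04 and Fdft1 at -0.62. The median of that list, -0.02, turned to 0.09 with the length and GC correction and differed in sign from its mean of 0.02 (camera adjusted p = 0.879). Lpl rose (1.28, SE 0.32) among 17 lipid droplet and uptake genes, whose median was -0.07 (camera adjusted p = 0.726). Icam1, an adhesion molecule (30.6 ± 4.96 against 12.7 ± 3.82 CPM; 1.27, SE 0.26), rose and Cxcl1 fell (-2.22, SE 0.54) among 12 inflammation genes, whose median was 0.49 (camera adjusted p = 0.285). Ndufs3 (-1.35, SE 0.37), Cox5a (-1.18, SE 0.34) and Atp5a1 (-0.67, SE 0.19) fell among 27 oxidative phosphorylation subunits, with a median of -0.28 (camera adjusted p = 0.0738).

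Of 69 named calls for B-LGND2, 26 were kept with any 1 library left out, among them Cd5l, C1qa, C1qb, C1qc, Marco, Tff3, Prtn3, Mmd2, Isyna1, Acadvl, Cyp3a25 and Esrrg, while for the others the adjusted p reached up to 0.208 (Kdr). The count of genes was 123, 100 and 184 without high fat vehicle replicate 1, 2 or 3, 134 and 421 without B-LGND2 replicate 1 or 3, and 1212 and 1439 without normal diet replicate 1 or 3. With the rRNA share as a covariate edgeR called 0 genes (417 under an unadjusted p of 0.05). Without scaling beyond library size the median log2 fold change of all genes was -0.18 and the calls split into 211 higher and 468 lower, 31.1% higher against 54.5% with scaling. The median transcript length was 2035 bases for protein-coding genes that rose and 3587 for those that fell.

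The third comparison set B-LGND2 on the high fat diet against vehicle on normal diet, to see how far treated livers stood from the normal diet. Cyp3a11 was 43.0-fold lower in treated livers, at 56.3 ± 10.2 against 2426 ± 584 CPM (n = 3 per group), and Cyp3a25 6.28-fold lower. Hmgcs1, the cytosolic HMG-CoA synthase of sterol synthesis, stood at 29.2 ± 9.42 against 84.7 ± 9.25 CPM. Macrophage genes were higher, with Cd5l at 406 ± 72.2 against 110 ± 30.0 CPM and Csf1r at 64.9 ± 14.95 against 17.2 ± 4.25 CPM. Myo15b had 145 counts in treated livers and 1 count on normal diet, a ratio of 133 with an exact 95% counting interval of 23.5 to 5296.

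In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 354 genes passed, 193 higher and 161 lower in treated livers. The groups did not overlap in 353 of them, and in 20.5% of all genes tested, where chance gives 10%. After Myo15b, the largest rises were in Slc34a2 (4.53, SE 1.01), Prtn3 (4.03, SE 0.50), Marco (3.98, SE 0.62) and Tff3 (3.91, SE 0.35, adjusted p = 2.18e-05), and the largest falls in Cyp3a11 (-5.43, SE 0.31, adjusted p = 4.22e-08), Cyp2c55 (-4.10, SE 0.49), Snord118, Cyp3a59 (-3.41, SE 0.43) and Snhg11 (-3.27, SE 0.59). Single libraries weighed on the size of some of these rises. In treated livers Slc34a2 stood at 3.01, 34.0 and 3.00 CPM and Marco at 6.49, 33.55 and 8.99 CPM. Prtn3 had 6, 4 and 32 counts on normal diet. Of 14 macrophage markers 10 rose and all were higher, with 13 higher adjusted over the list alone and a median of 1.41 (camera adjusted p = 1.76e-20; adjusted p = 0.0523 with an estimated correlation). Lyve1 (1.37, SE 0.27), Cdh5 (1.02, SE 0.23) and Stab2 (0.88, SE 0.22) rose among 11 endothelial markers, with 3 higher adjusted over the list alone and a median of 0.46 (camera adjusted p = 0.00129; adjusted p = 0.345 with an estimated correlation). Tgfb1, encoding transforming growth factor beta 1, rose (1.36, SE 0.31) among 17 matrix genes, with 4 higher adjusted over the list alone and a median of 0.49 (camera adjusted p = 0.00230; adjusted p = 0.345 with an estimated correlation). None of 10 stellate markers passed edgeR (5 under an unadjusted p of 0.05, 2 by DESeq2). Their list had a median of 0.67 (camera adjusted p = 0.0240; adjusted p = 0.239 with an estimated correlation), and its call was lost without normal diet replicate 2 (0.0700) or B-LGND2 replicate 3 (0.113).

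Metabolic lists were lower in treated livers than on normal diet. In the xenobiotic list 9 of 20 fell, among them Cyp3a11, Cyp3a25 (-2.65, SE 0.25) and Ces2a (-1.97, SE 0.25), 10 were lower adjusted over the list alone, and the median was -0.75 (camera adjusted p = 2.38e-18; adjusted p = 0.0523 with an estimated correlation). Fdft1 (-1.33, SE 0.25), Hmgcs1 (-1.54, SE 0.31), Msmo1 (-1.22, SE 0.28) and Cyp51 (-1.30, SE 0.31) fell among 24 sterol genes, 9 were lower adjusted over the list alone and the median was -0.67 (camera adjusted p = 1.31e-07; adjusted p = 0.394 with an estimated correlation). Gsta4 (-1.99, SE 0.27), Ugdh, Ephx1 and Gclc, the catalytic subunit of glutathione synthesis (-0.94, SE 0.21), fell among 9 targets of the oxidative stress factor NRF2, with 4 lower and 1 higher adjusted over the list alone and a median of -0.67 (camera adjusted p = 1.26e-04; adjusted p = 0.185 with an estimated correlation). Atp5c1 fell (-1.19, SE 0.26) among 27 oxidative phosphorylation subunits, of which 26 were lower and 4 passed adjusted over the list alone, with a median of -0.42 (camera adjusted p = 1.27e-05; adjusted p = 0.345 with an estimated correlation). Cyp4a12a (-2.62, SE 0.31) and Cyp4a12b (-2.64, SE 0.38) fell among 14 male-biased genes, with 2 lower and 1 higher adjusted over the list alone. The median of that list was -0.16 (camera adjusted p = 0.0386, and 0.538 with an estimated correlation). With the length and GC correction the median turned to 0.20 and the call was lost (camera adjusted p = 0.587). It was also lost without normal diet replicate 1 (0.0923) or B-LGND2 replicate 2 (0.334).

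Other lipid and inflammation lists did not pass camera in this comparison. Srebf1, the lipogenic transcription factor, rose (1.06, SE 0.24) and Acss2 fell (-1.11, SE 0.28) in the lipogenic list (camera adjusted p = 0.635), Cyp4a10 (-2.67, SE 0.46) and Hadhb (-1.79, SE 0.42) fell in fatty acid oxidation (0.0766), Pparg fell (-1.60, SE 0.36) in lipid droplets and uptake (0.293), and Vcam1 rose (1.12, SE 0.26) in inflammation (0.0751). Of 40 named calls, 19 were kept with any 1 library left out, among them Cyp3a11, Cyp3a25, Cyp2c55, Tff3, Prtn3, Cd5l, Csf1r, Fdft1 and Gsta4, while for the others the adjusted p reached up to 0.204 (Slc34a2). The count of genes was 639, 111 and 224 without normal diet replicate 1, 2 or 3, 234, 228 and 235 without high fat vehicle replicate 1, 2 or 3, 130 and 221 without B-LGND2 replicate 1 or 2, and 21 with the rRNA share as a covariate.

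The design also asks whether B-LGND2 moved the diet's genes back. Of the 362 genes called for diet, 332 (91.7%) had a fold change of the opposite sign with B-LGND2. The Wilson 95% interval of 88.4 to 94.1 takes the genes as independent, which they are not, and leaves out the spread between mice. Both contrasts use the same high fat vehicle libraries, with opposite sign. Simulations without a ligand effect, whose contrasts also shared a high fat vehicle group, gave 58.2% on average (51.9% to 65.3% over 50 simulations). All 9 libraries were drawn anew each time, so the observed values of the high fat vehicle libraries were not kept. The simulations drew each gene on its own, without the length and rRNA trends of the libraries, and gave called genes their observed diet effect. The simulated values may therefore understate what the shared libraries give. Called in both contrasts and in opposite directions were 101 genes, 59 of them higher on the high fat diet and lower with B-LGND2 and 42 the reverse (55 and 21 among protein-coding genes), where independent lists would share 10.2. The simulations gave at most 1, a count near 0 by construction, since groups without a ligand effect have almost no calls, and it is no measure of the overlap of real calls. Part of the excess may come from the shared libraries, and with 3 of them no split gives each contrast 2 libraries of its own. The covariance of the log2 fold changes over all genes tested was -0.222 against -0.0717 in the simulations, a difference of -0.150, and their correlation across genes -0.541 against -0.404.

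The 10 genes of this kind with the smallest p were CT010467.1, annotated as rRNA (log2 fold changes -1.66 and 2.38), Gm26917 and Gm42418, noncoding models beside or overlapping it on chr17, the small noncoding models Gm23935, Gm24187 and Gm24270, Lars2 (-3.08 and 3.22), Csad, the taurine synthesis enzyme (-2.04 and 1.54), Per1 (1.35 and -1.18) and Zbtb16 (2.40 and -1.40). Among the 101 were 14 pseudogenes and 76 protein-coding genes of 292 called for diet. Grouped in the analysis as rRNA-like were 8 of the 101. They were CT010467.1, Gm26917, Gm42418, Gm23935, Gm24187, Gm24270, Gm15564 and Lars2, which is also counted as protein coding. In the diet and B-LGND2 contrasts all 8 moved as the rRNA share did, so these changes cannot be told apart from it. Against normal diet the share was higher in treated livers, but Gm15564 was lower there (-1.24, edgeR adjusted p = 0.0454). The other rRNA-like models were not called in that comparison. Cyp3a11, Cyp3a25 (-1.08 and -1.57) and Akr1c19 (-1.17 and -0.96) were called for diet and for B-LGND2 in the same direction. Independent lists would share 10.2, a count that leaves out the shared libraries. Simulated groups without a ligand effect shared 0, a count near 0 by construction. Neither value tells whether 3 such genes are few or many. These 3 genes were named after their values were seen. Between high fat vehicle and normal diet on one side and treated livers and normal diet on the other, 54 genes were called in the same direction, where independent lists would share 5.30. Between B-LGND2 against vehicle and treated livers against normal diet, 145 genes were called in the same direction and 2 in opposite directions, where independent lists would share 10.04 in the same direction. Simulated groups without any effect shared at most 1 call in either pair, again near 0 by construction, and part of both overlaps may come from the shared libraries.

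**Figure D4:**
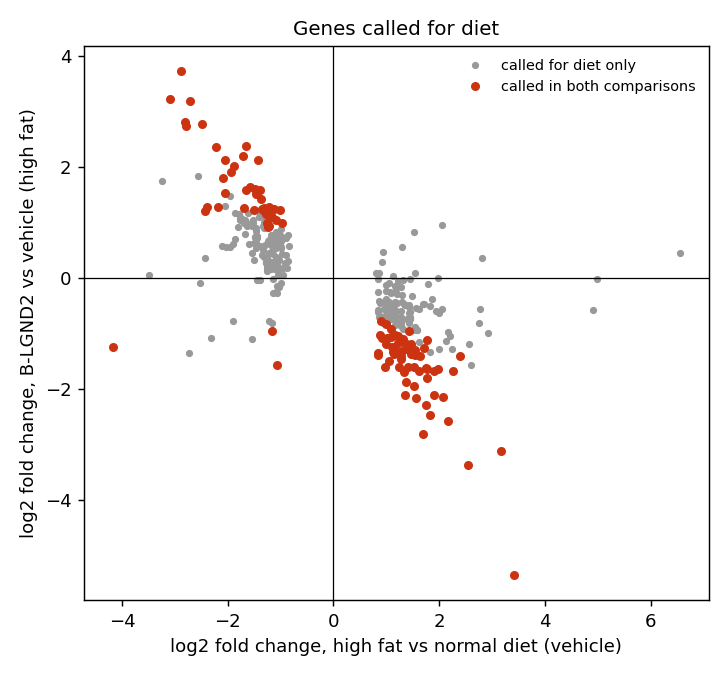
Log2 fold change with B-LGND2 (y axis) against that with the high fat diet under vehicle (x axis) for the 362 genes called for diet; points are genes, and red points the 104 called in both contrasts. Of the red points, 101 lie in the quadrants of opposite sign and 3 in that of 2 falls.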

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

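Tests of transcript length and GC content, of the rRNA share and of other splits of the libraries were chosen after the results were seen. The test with different high fat vehicle libraries was written down beforehand.

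A signal stood out in gene models outside the mRNA measurement: the rRNA share of counts averaged 5.52% with B-LGND2, above the vehicle groups at 3.42% on normal diet and 1.20% on high fat diet.

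Each contrast has 10 splits of its 6 libraries into groups of 3. In 1 of 10 splits, the real one, as many genes were called as reported for each contrast; the most in any other split was 0 for diet, 0 for B-LGND2 against vehicle and 1 for treated livers against normal diet. Those other splits had 111 to 1163, 156 to 539 and 335 to 1571 genes under an unadjusted p of 0.05. With 10 splits, a chance difference between the groups is neither excluded nor shown.

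The opposite signs of diet and B-LGND2 effects, in 332 of 362 genes called for diet (91.7%, against 51.9% to 65.3% in 50 simulations without a ligand effect or library trends), can be set against 3 technical explanations and the biological one the design offers, a return of diet effects by the ligand. Transcript length and GC bias as the whole cause was argued against: 61 of the 101 genes called in both contrasts in opposite directions (60.4%) stayed so with a correction for both. A part of such bias in the pattern stays open. Log2 fold changes of protein-coding genes correlated with transcript length at 0.441 for diet and -0.280 for B-LGND2. The part that chance values of the shared high fat vehicle libraries have in it stays open: when the diet call used 2 of these libraries and the ligand contrast the third alone, 85.7%, 69.7% and 87.2% of 35, 66 and 39 genes kept opposite signs, all above the 50% that chance values alone would give, and the lowest under the bound of 75% set beforehand. A trait of library preparation that the rRNA share marks cannot be told apart from the groups, which explained 94.5% of the variance of the log2 rRNA share, and with that share as a covariate 0 genes were called for diet. Part of the opposite signs may therefore come from the high fat vehicle libraries, and a reversal by B-LGND2 stays an untested hypothesis.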

How the results depend on the processing

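The length and GC correction, the protein-coding filter and the rRNA covariate were chosen after seeing the data; the other alternatives were planned. With 1 library of 9 left out, the counts of genes ran from 35 (without high fat vehicle replicate 1) to 1860 (without normal diet replicate 1) for diet, 100 (without high fat vehicle replicate 2) to 1439 (without normal diet replicate 3) for B-LGND2 against vehicle, and 111 (without normal diet replicate 2) to 639 (without normal diet replicate 1) for treated livers against normal diet. Also over 1.5 times from the reported count were diet without normal diet replicate 2 (89) or 3 (79) and high fat vehicle replicate 2 (66) or 3 (39); B-LGND2 without normal diet replicate 1 (1212), high fat vehicle replicate 1 (123) or 3 (184), or B-LGND2 replicate 1 (134) or 3 (421); and treated livers without normal diet replicate 3 (224), high fat vehicle replicate 1 (234), 2 (228) or 3 (235), or B-LGND2 replicate 1 (130) or 2 (221). In the order diet, B-LGND2, treated livers, genes called were 1182, 1345 and 751 without a low-count filter, 984, 1123 and 660 by DESeq2, 153, 1420 and 144 with only the 2 groups compared, and 0, 0 and 21 with the rRNA covariate (486 and 417 under an unadjusted p of 0.05 where 0 were called). The covariate is nearly fixed by group and raised the SE 3.08-fold at the median; for the other moves the cause was not tested. DESeq2 size factors gave 366, 659 and 357 genes, the 50-count filter 347, 539 and 286, limma-voom 329, 627 and 332, no robust option 351, 633 and 342, no scaling 358, 679 and 266, the length and GC correction 255, 915 and 329, and protein-coding genes only 333, 637 and 408. With the replicate block the counts were 203, 492 and 253. The deviations of same-numbered libraries from their group means correlated at -0.194 to 0.0232 for replicate 1 and -0.0730 to 0.0594 for replicate 3. For replicate 2 the correlations were all positive, at 0.0325 to 0.124.

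Gene lists called were 0 in each contrast with an estimated correlation (smallest adjusted p = 0.548, 0.0723 and 0.0523 by camera) and 10 for diet with the rRNA covariate. They ran from 5 to 9, 7 to 11 and 8 (without normal diet replicate 2) to 14 (without B-LGND2 replicate 1) with a library left out. With a library left out, the share of diet genes with opposite sign under B-LGND2 ran from 85.4% (without normal diet replicate 2) to 92.3% (without high fat vehicle replicate 3); it was 92.9% with the length and GC correction, and the rRNA covariate gave no value, since no diet gene was called.

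Of 238 named results, 16 turned direction under an alternative, all with the rRNA covariate: for diet Me1 0.54, Mlxipl -0.56 and CT010467.1 0.10; for B-LGND2 Slc34a2 -4.20, Myo15b -3.40, Tgfbr3l 2.69, Col4a2 -0.40, Ciart 0.28, Nr1d1 2.86, Per3 1.17, Lyve1 -0.29, Mlxipl 0.98, Insig1 2.03, Ndufs3 0.70, Atp5c1 0.41 and CT010467.1 -0.21. List medians turned to 0.42 for xenobiotic metabolism (diet), -0.40 for matrix genes and 0.22 for clock genes (B-LGND2), and 0.32 for male-biased genes (treated livers). Of 163 calls of named genes, 145 were lost and 9 reversed with the rRNA covariate, 33 were lost with only the 2 groups compared, 30 with the block, 28 with the length and GC correction and 19 without scaling, and with a library left out 424 of 1467. Depth of 5778978 to 10322972 counts leaves genes at a few counts per library untested.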

Other observations

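Of the tests here, only that of glucocorticoid targets was written down before its result, and the genes in the next paragraph were named after their values were seen.

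Several single genes changed with B-LGND2 against vehicle on the high fat diet. Cyp17a1, the 17-hydroxylase of steroid synthesis, rose to 75.3 ± 21.5 from 14.6 ± 12.9 CPM (log2 fold change 2.37, SE 0.46, n = 3 per group), Hsd17b2, which oxidises estradiol, rose to 331 ± 34.4 from 141 ± 27.3 CPM (1.23, SE 0.22), and Akr1d1, the 5-beta reductase of bile acid synthesis, fell to 25.9 ± 5.83 from 81.5 ± 16.3 CPM (-1.65, SE 0.24). Apoc2, the activator of lipoprotein lipase, rose to 660 ± 156 from 227 ± 8.24 CPM (1.54, SE 0.29), Apoc3 rose (1.18, SE 0.30), and the bile salt and anion transporter genes Slco1b2 (-0.91, SE 0.22) and Abcc3 (-1.06, SE 0.27) fell. Ucp2, a mitochondrial carrier (1.21, SE 0.26), and Saa3, an acute phase gene of macrophages (2.19, SE 0.41), rose. The lists that some of them belong to did not pass camera: 3 of 20 genes of bile acid metabolism and transport fell (median -0.29, camera adjusted p = 0.0515; adjusted p = 0.367 with an estimated correlation; 0.00405 by limma's rotation test fry, which called the list), and 3 of 19 lipoprotein genes rose (median 0.35, camera adjusted p = 0.158; adjusted p = 0.607 with an estimated correlation; 0.236 by fry). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p ran from 0.00163 for Akr1d1 to 0.0344 for Apoc3. With any 1 library left out, the calls of Akr1d1, Apoc2 and Saa3 were kept. Hsd17b2 (-1.02) and Saa3 (-1.72) were also called lower on the high fat diet under vehicle. In treated livers neither was called against normal diet (0.21 and 0.47, edgeR adjusted p = 0.635 and 0.507). Socs3, an inhibitor of cytokine signalling, rose with the diet under vehicle, to 39.5 ± 10.8 from 13.7 ± 0.966 CPM (1.53, SE 0.33, edgeR adjusted p = 0.0253), and stood at 70.5 ± 36.2 CPM in treated livers, where the difference from high fat vehicle did not pass (0.83, SE 0.31, edgeR adjusted p = 0.116).

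The higher macrophage markers with B-LGND2 were set against 3 explanations. A lower share of hepatocytes as the whole cause was argued against, since the macrophage score rose by 1.53 and the endothelial and stellate score by 0.42, a rise of 1.11 beyond them, with scores of 0.69 ± 0.21 and -0.42 ± 0.15 for the difference. Transcript length and GC bias was argued against, with a list median of 1.41 after the correction and 11 members called. A single fold change common to all macrophage markers was argued against by the spread of their fold changes (heterogeneity p = 1.80e-04 without Mpeg1, by a chi-square test over n = 13 markers with their SEs). That test cannot decide on more cells of one kind, since in whole tissue a marker also expressed by other cells would change less. More macrophages, a change in their kind or state, or a mix of both may be behind the pattern, and these were not told apart. The trait that the rRNA share marks stays open too. With that share as a covariate the macrophage list kept its camera call at the preset correlation, but the covariate is nearly fixed by group.

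The higher clock, immediate early and gluconeogenic genes on the high fat diet raised the hypothesis of a stronger glucocorticoid response. Of 11 other glucocorticoid targets, a list chosen after the pattern was seen, 8 were higher and Arrdc2 (1.34, SE 0.31) and Errfi1 (0.99, SE 0.23) rose, with a median of 0.67 (camera p = 0.00128; p = 0.0229 with an estimated correlation), which is consistent with it. Mt1 (-1.09) and Mt2 (-1.08), also targets, were lower without passing. A different hour of tissue collection stays open: clock genes with a later daily peak had a median 0.35 above those with an earlier peak (exact permutation p = 0.339 over 12 genes), and the hour is not given in the sources used here. Handling stress, fasting before collection and the diet itself may each give such a response and were not told apart.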
